A study of Mus musculus with 5 samples.

How the data were processed

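The data are RNA sequencing of whole lung from female wild-type BALB/c mice, with 5 groups and 1 library per group. The labels name a control group, mice given PM10 (inhalable airborne particulate matter), mice given PM10 and ovalbumin (OVA, a protein allergen), and mice given both together with either a chitinase-1 inhibitor, abbreviated CPX, or dexamethasone (Dex), a synthetic glucocorticoid. Per the series' design text, PM10 was given into the nose 4 times over 2 weeks, OVA was injected and then given into the nose, the inhibitor was injected 6 times over 3 weeks and dexamethasone 3 times in the last week, and lungs were taken 2 days after the last challenge. Doses, and whether a library came from 1 animal or from pooled animals, are not given in the sources used here.

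Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1.3 ug of total RNA with the NEBNext Ultra II Directional kit, which keeps the strand of the transcript. Per the submitters' processing notes, reads were aligned with TopHat to mm10. The version of the aligner, the counting tool, the gene annotation and the strand setting of the counting are not given in the sources used here. The files the authors deposited hold whole-number read counts per gene symbol, 1 file per library, with no normalization. Each lists 23183 symbols, of which 4774 were at 0 in all 5 libraries. How the authors' counting treated reads that fit several genes is not known, so levels of near-identical genes (Chil3 and Chil4, the Ear genes, Saa1 and Saa2, the haemoglobin genes, the Mcpt genes, Amd1 and Amd2, Atp6v0c and its pseudogenes, the Bpifa genes) are uncertain, as are overlapping and antisense genes. The same holds for the related heat-shock genes Hspa1a and Hspa1b, whose folds may not be separate values.

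Library totals were 16929068 counts for control, 12038105 for PM10, 16036136 for PM10/OVA, 12612578 for PM10/OVA/CPX and 11993222 for PM10/OVA/Dex. A single count was worth between 0.0577 and 0.0841 CPM (counts scaled to a common library total), and the floor set for a count of 0, 3 counts, is 0.173 to 0.252 CPM. The 10 most abundant genes took between 7.39% and 8.30% of each library. Xist, the transcript of the inactive X chromosome, was at 249 to 422 CPM in every library.

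Counts were scaled to CPM with trimmed-mean-of-M-values (TMM) factors over the 5 libraries (edgeR 4.0.16 in R 4.3.3). The factors ran from 0.989 to 1.02. A gene counted as measured with a mean of at least 1 CPM over the 5 libraries, which left 14305 genes. The log2 ratio of 2 libraries was taken on log2(CPM + 1), which understates differences of low genes, and genes at least 2-fold higher or lower on that scale were counted. Folds of named genes are ratios of CPM with an exact (Clopper-Pearson conditional) 95% interval from the counts. These intervals and the floors cover counting error only. Against a library at 0 counts the fold is a lower bound, computed with 3 counts in that library. It leaves out the counting error of the other library, so the lower limit of the exact interval, given beside it, is smaller. With 1 library per group there are no replicates, so no p-value, standard error or test between conditions was computed, and no difference has a replicate check. Beside each count of genes stands the count from 100 simulations in which both libraries had equal levels and Poisson counting error at the real depths.

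The 46 gene lists (cell types, pathways, responses, and tissues that border the lung) were fixed before the data were examined, and 44 of them had at least 4 measured members. Medians and member counts of a list cover its measured members only. The median log2 ratio of each list was placed among the medians of 10000 random lists of the same size matched on mean expression in 20 bins. A list is said to stand apart when its percentile was at most 2.5 or at least 97.5. This percentile is a description of these libraries. Of 44 lists of randomly drawn genes, 2.2 are expected outside these bounds in each comparison. Members of a fixed list can move together between lungs, which random lists do not hold. The value of 2.2 is therefore not a chance rate for the fixed lists. Genes were named by a rule that was also fixed beforehand. It takes, per comparison, the 10 highest and the 10 lowest log2 ratios outside predicted models, small RNAs and receptor segments, the chitinase genes Chit1, Chia1, Chil1, Chil3 and Chil4, and up to 4 members with the largest absolute ratio in each list described.

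The 6 comparisons were PM10 against control, PM10/OVA against PM10, PM10/OVA against control, CPX against PM10/OVA, Dex against PM10/OVA and Dex against CPX. Genes that differed between PM10/OVA and control were then followed under both treatments as a median log2 ratio. Since the PM10/OVA library enters both ratios, the value simulated with counting error and no treatment effect is given beside it, which leaves out differences between lungs, and the same was done with pairings that share no library. The interval of such a median is a binomial order-statistic 95% interval that treats genes as units. It describes the spread over genes, not over animals. The percent of followed genes with a ratio below 0 was added after the data had been examined.

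The calculations were first tested on simulated counts with 200 altered genes. Of 100 genes altered 3-fold, 95, 89, 94, 94, 94 and 96 were recovered in the 6 comparisons in the order above, and of 100 altered 6-fold, 99, 98, 100, 100, 99 and 100. At most 2 of 14105 unaltered genes were called, and 3 to 5 of 100 lists of randomly drawn unaltered genes stood apart. Counts were simulated independently for each gene, so lists whose members move together were not covered.

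Alternatives fixed beforehand were total-count scaling, DESeq2 1.42.0 size factors, pseudocounts of 0.25 and 5, no filter or a mean of at least 5 CPM, leaving out receptor segments, haemoglobin and mitochondrially encoded genes before scaling, and picking the followed genes at 1.5-fold or 4-fold. Only haemoglobin genes were matched by the step that leaves genes out. Added after seeing the data were leaving out the heart, skeletal muscle, fat and cartilage list genes, removing the trend of the ratio with transcript length and GC content, random lists matched on length, and exchanging the labels of the CPX and PM10/OVA libraries for the followed genes. Gene positions, lengths and GC content come from GENCODE mouse release 21 (GRCm38, the assembly of mm10), in which 14196 of the 14305 measured symbols (99.2%) were matched. Further steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and statsmodels 0.14.6.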

Results

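Whole-lung RNA of female BALB/c mice was sequenced in 5 groups, control, PM10, PM10/OVA, PM10/OVA/CPX and PM10/OVA/Dex, with 1 library per group. Library totals ran from 11993222 to 16929068 counts, and 14305 genes were measured. The series title places the study in airway inflammation and fibrosis and in the suppression of chitinase-1. No group has replicates, so every difference is between libraries and has no replicate check. Folds are ratios of TMM-scaled CPM with a 95% counting interval, and list medians are log2 ratios. All 10 pairs of libraries differed by at least 2-fold in between 200 and 844 genes, where counting error alone gave at most 3 genes in either direction in any simulation of the 6 comparisons.

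Chitinase genes come first, as the target that the labels name. Chit1, the gene of chitinase-1 (GRCm38 chromosome 1, 134111242 to 134151540, protein-coding), had 0 counts in all 5 libraries. The floor of 3 counts is 0.173 CPM in control and 0.252 CPM in PM10/OVA/Dex, with exact 95% upper limits of 0.213 and 0.310 CPM from counting error alone, but whether the transcript was absent or its reads were lost in the counting is not known. The genes of related proteins were abundant and differed between libraries. Chil1, a chitinase-like lectin without enzyme activity (chromosome 1, 134182176 to 134190181), was at 499 CPM in control, 2065 in PM10, 3067 in PM10/OVA, 2611 in PM10/OVA/CPX and 1533 in PM10/OVA/Dex. Chia1, the acidic mammalian chitinase (chromosome 3, 106113229 to 106132120), was at 79.9, 57.9, 157, 596 and 268 CPM in the same order. Chil3 (chromosome 3, 106147554 to 106167564) was at 108, 309, 510, 4455 and 1427 CPM. Its neighbour Chil4 (chromosome 3, 106201490 to 106219507) had 0 counts in control and PM10, 56 counts in PM10/OVA, 6345 in PM10/OVA/CPX and 485 in PM10/OVA/Dex. Against control, Chil4 was at least 20.4-fold higher in PM10/OVA, at least 2929-fold higher in PM10/OVA/CPX and at least 236-fold higher in PM10/OVA/Dex, with exact lower limits of 16.1, 2381 and 191. Chil3 and Chil4 are close paralogs, and their reads may be split unevenly between them. Chid1 and Ctbs, the other measured members of this list, stayed between 28.7 and 39.3 CPM and between 19.0 and 23.1 CPM.

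**Figure D1:**
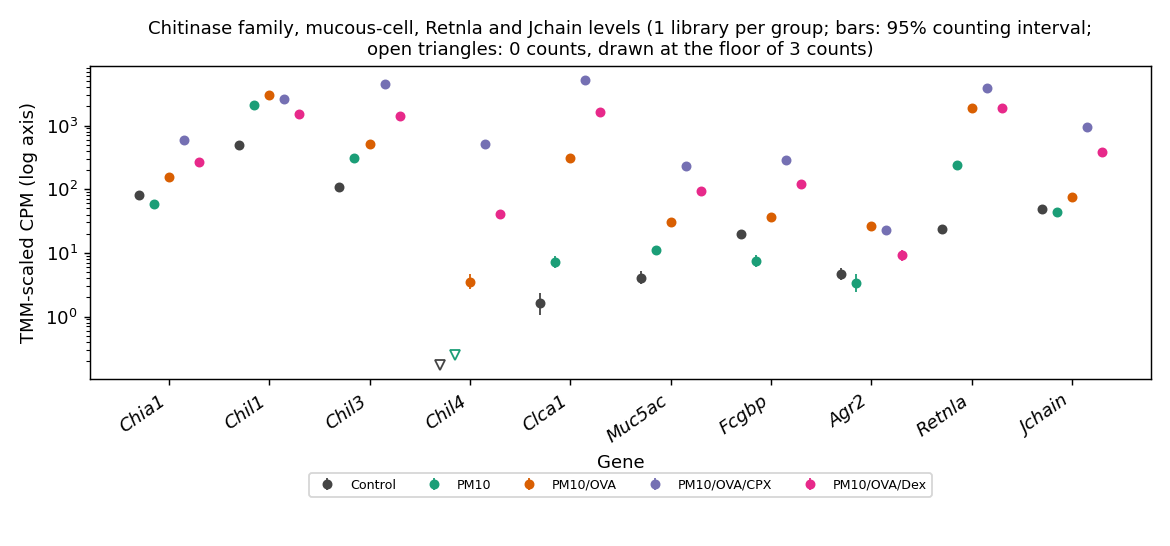
Levels of chitinase-family, mucous-cell, Retnla and Jchain genes in TMM-scaled CPM on a log axis, 1 point per library, with bars for the 95% counting interval and open triangles for 0 counts drawn at the floor of 3 counts. Chil3 (4455 CPM), Chil4 (507 CPM) and Clca1 (5154 CPM) were highest in the PM10/OVA/CPX library, while Chil1 was highest in PM10/OVA (3067 CPM).

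PM10 against control asks what the particles alone did in the lung. Acute-phase, neutrophil-attracting and interferon-response genes were higher in the PM10 library. Saa3, an acute-phase protein (chromosome 7, 46711998 to 46715700), was 211-fold higher (interval 154 to 299, 5592 counts against 38). Lcn2, an iron-binding antibacterial protein, was 14.3-fold higher (13.5 to 15.2). Irf7, a transcription factor of the interferon response (chromosome 7, 141262706 to 141266481), was 16.8-fold higher (15.3 to 18.5), and Irg1, annotated as Acod1, the enzyme that makes itaconate in activated macrophages, was 425-fold higher on 592 counts against 2 (117 to 3520). Heart-muscle, fat and cartilage genes were lower, led by the atrial hormone Nppa at 128-fold (98.7 to 170). In all, 529 genes were at least 2-fold higher and 292 at least 2-fold lower (304 and 141 with a pseudocount of 5, and 146 lower with a mean of at least 5 CPM), where counting error alone gave means of 0.08 and 0.11. Of the 44 lists, 19 stood apart as higher and 13 as lower.

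The interferon-response list had the highest median, 2.48, with 25 of 28 members at least 2-fold higher and the remaining 3 also above 0. Cxcl10 (19.9-fold, 12.9 to 32.2) and Cxcl9 (18.8-fold, 11.5 to 32.8), which attract T cells, and the antiviral gene Oas3 (11.3-fold, 9.19 to 13.9) were among them. Monocyte and interstitial macrophage genes had a median of 1.51, with 16 of 20 members at least 2-fold higher, such as Gpnmb (13.5-fold, 11.8 to 15.4) and the antibody receptor Fcgr1 (6.67-fold, 5.48 to 8.17). Cell cycle genes had the same median, 1.51, with 22 of 28 at least 2-fold higher, including Mki67 (4.34-fold, 3.89 to 4.85) and Top2a (4.52-fold, 3.94 to 5.20). Complement and acute-phase genes (median 1.12) had 9 of 16 members at least 2-fold higher, Cfb among them at 9.24-fold. In the list of neutrophil chemokines and IL-1, IL-6, TNF and IL-17 cytokines (median 0.95), 8 of 16 were, with Cxcl5 at 62.5-fold on 174 counts against 4 (24.0 to 232) and Cxcl3 at 117-fold on 245 against 3 (39.7 to 573). Alveolar macrophage genes (0.94) had 8 of 17 members higher, such as Marco (11.8-fold), and 2 lower, including Fabp4 (7.54-fold), which is also a fat-cell gene. Neutrophil genes had a median of 0.70, although Ltf, a granule protein, was 4.41-fold lower. Class II antigen presentation (0.69), dendritic cell (0.53), metal-response (0.49), type 2 (0.47), T cell (0.37), alveolar type 2 (0.27), endoplasmic reticulum stress (0.26), alternatively activated macrophage (0.25), glucocorticoid-responsive (0.23) and mucous-cell genes (0.16) also stood apart as higher, with the regulatory T cell gene Ctla4 at 4.83-fold (2.97 to 8.17). The mucous-cell list no longer stood apart with a pseudocount of 5 (0.0693), without a filter (0.13), with a mean of at least 5 CPM (0.16) or with the length and GC trend removed (0.15).

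Among matrix genes, the metalloproteinase list had a median of 0.42, with Mmp12, a macrophage elastase, 23.5-fold higher (19.2 to 29.2) and Timp1, an inhibitor of such enzymes, 13.8-fold higher (9.99 to 19.5). Fibrillar collagen and matrix genes had a median of 0.28 at percentile 99.99, with 1 of 26 members at least 2-fold higher, Lox (2.10-fold), and 2 lower, Thbs2 (2.98-fold) and Lum (2.29-fold). The TGF-beta and myofibroblast list did not stand apart (median 0.00, percentile 41.7).

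The lower lists were led by fat (median -2.57, 12 of 13 members at least 2-fold lower), cartilage (-2.57, 8 of 9) and heart muscle (-1.93, 18 of 19). Thrsp, a lipogenic gene, was 14.9-fold lower (12.1 to 18.6), Acan, the cartilage proteoglycan, 10.8-fold lower (7.81 to 15.2) and Mb, myoglobin, 11.5-fold lower (9.95 to 13.4). The atrial growth factor Bmp10 had 0 counts in PM10 against 154, at least 35.7-fold lower against the floor of 3 counts (exact lower limit 28.7). Lower with them were smooth muscle genes (-0.79, 3 of 14 at least 2-fold lower, such as Cnn1), club cell genes (-0.51, Cyp2a5 8.36-fold lower) and ciliated cell genes (-0.42, all 19 below 0, none by 2-fold). Bpifa1, a secreted protein of the upper airways, was 17-fold lower (15.9 to 18.2) and Krt15, a basal-cell keratin, 18.2-fold lower (10.5 to 34.5). Skeletal muscle (-0.43), mesothelial (-0.39), erythroid (-0.37), B cell (-0.36), circadian clock (-0.28), endothelial (-0.26) and alveolar type 1 genes (-0.20) stood apart as lower as well. Aryl hydrocarbon receptor targets (median -0.08, mean 0.03, percentile 21.6) and NRF2 targets (median 0.06, percentile 80) did not stand apart.

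**Figure D2:**
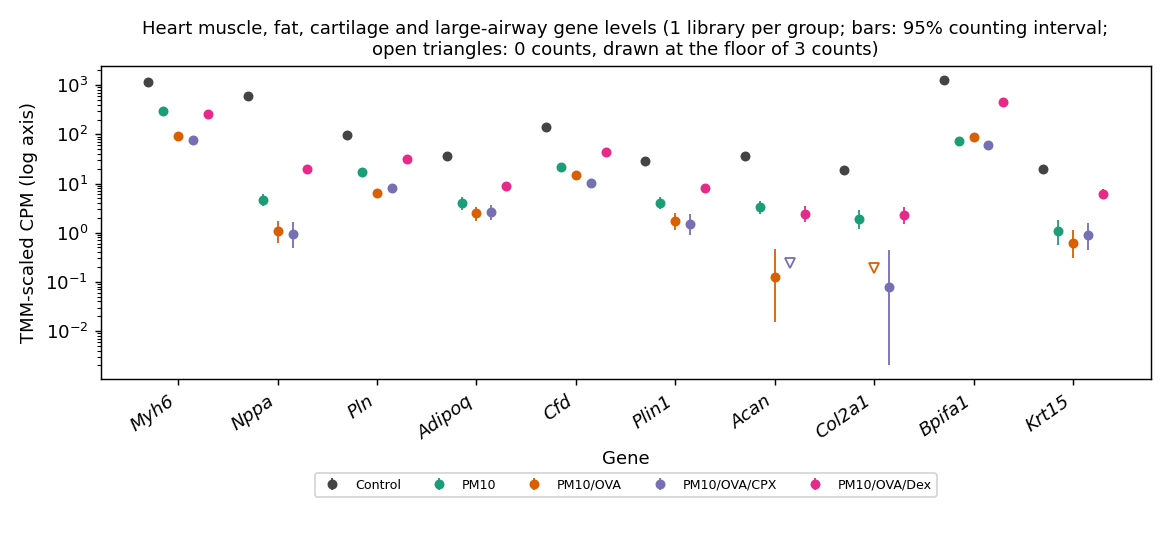
Levels of heart-muscle, fat, cartilage and large-airway genes in TMM-scaled CPM on a log axis, 1 point per library, with bars for the 95% counting interval and open triangles for 0 counts drawn at the floor of 3 counts. Each gene was highest in the control library, such as Myh6 at 1182 CPM, against 92.3 CPM in PM10/OVA and 264 CPM in PM10/OVA/Dex.

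PM10/OVA against PM10 asks what the allergen added to the particles. Mucous-cell, alternatively activated macrophage, eosinophil-attracting and neutrophil genes were higher, and interferon-response and cell cycle genes were lower. Clca1, a secreted product of mucous cells (chromosome 3, 145003817 to 145032776), was 43.9-fold higher (35.5 to 55.0), Arg1, which breaks down arginine (chromosome 10, 24915221 to 24927484), 35-fold higher (25.2 to 50.2), and Retnla 7.67-fold higher (7.38 to 7.97). Irf7 was 10.6-fold lower (9.77 to 11.5). At the 2-fold threshold 99 genes were higher and 182 lower (173 and 308 with a pseudocount of 0.25, 54 and 78 with 5), against means of 0.30 and 0.10 from counting error, and 15 lists stood apart as higher and 13 as lower.

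Neutrophil genes had the highest median, 1.09, with 8 of 14 members at least 2-fold higher, such as S100a8 (3.78-fold, 3.40 to 4.21) and Mmp9 (2.94-fold, 2.47 to 3.50). The mucous list (0.91, 8 of 18) included Agr2, which folds mucins, at 7.67-fold (5.56 to 10.8) and the anion exchanger Slc26a4 at 4.62-fold (4.02 to 5.32). The neutrophil chemokine and cytokine list (0.82, 7 of 16) included Cxcl5 at 5.09-fold (4.34 to 6.01). Chitinase genes had a median of 0.65 and eosinophil genes of 0.62, with 5 of 11 eosinophil members at least 2-fold higher, among them Ccr3, the eotaxin receptor, at 2.84-fold (2.20 to 3.70). With only genes of a mean of at least 5 CPM the eosinophil median was 0.04 and the list no longer stood apart, nor did metalloproteinase genes without a filter (0.0196). Type 2 genes (0.58, 5 of 14) included the eosinophil chemokines Ccl11 (5.48-fold, 4.18 to 7.31) and Ccl24 (9.84-fold, 5.47 to 19.4). The type 2 list was fixed with more members, and only the 14 measured ones enter its values. Erythroid (0.58), B cell (0.53), alternatively activated macrophage (0.51), endoplasmic reticulum stress (0.48), plasma cell (0.47), mast cell and basophil (0.30), NRF2 target (0.28), smooth muscle (0.25) and metalloproteinase genes (0.23) were higher as well, with Timp1 at 3.31-fold (2.96 to 3.70) and the NRF2 target Slc7a11, a cystine transporter, at 1.82-fold (1.63 to 2.04).

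In the interferon-response list 18 of 28 members were at least 2-fold lower (median -1.72), such as Ifi44 (6.54-fold, 5.93 to 7.23) and Oasl2 (5.0-fold, 4.60 to 5.43). In the cell cycle list 10 of 28 were (-0.84), with Cenpf at 5.02-fold (3.84 to 6.65). Heart muscle (-1.01, 10 of 19), cartilage (-0.57) and fat genes (-0.32) were again lower, Ryr2, a calcium channel, by 3.91-fold (3.12 to 4.95). Cartilage (-0.15) and fat genes (-0.12) did not stand apart with a pseudocount of 5, nor class II genes with a pseudocount of 0.25 (-0.17) or a mean of at least 5 CPM (-0.12). Standing apart beside them were circadian clock (-0.45), monocyte (-0.36), fibroblast (-0.30), alveolar macrophage (-0.26), glucocorticoid-responsive (-0.19), TGF-beta (-0.18), class II (-0.17) and immediate-early and heat-shock genes (-0.14). Of the heat-shock genes Hspa1b was 9.16-fold lower (7.58 to 11.1) and Hspa1a 8.04-fold lower (6.5 to 10). Across genes the ratio was lower for longer transcripts (Spearman's rho -0.33 over 14196 genes, which are not independent replicates).

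PM10/OVA against control covers both exposures together. Saa3 was 317-fold higher (230 to 448), Clca1 194-fold (134 to 292), Retnla 78.4-fold (71.1 to 86.6), Timp1 45.6-fold (33.5 to 63.8) and Arg1 41.2-fold (30.5 to 56.9). Nppa was 555-fold lower (346 to 952). At the 2-fold threshold 454 genes were higher and 390 lower (261 and 203 with a pseudocount of 5, and 208 lower with a mean of at least 5 CPM), against means of 0.01 and 0.03 from counting error, and 24 lists stood apart as higher and 11 as lower.

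The highest medians were those of neutrophil chemokines and cytokines (2.05, 11 of 16 members at least 2-fold higher), neutrophil genes (1.92, 11 of 14), chitinase genes (1.57, 3 of 6), monocyte and interstitial macrophage genes (1.40, 13 of 20) and mucous-cell genes (1.35, 11 of 18). Cxcl5 was at 1164 counts against 4, 318-fold higher (124 to 1170), and the neutrophil receptor Cxcr2 was 5.14-fold higher (4.37 to 6.07). Muc5ac, the gel-forming airway mucin, was 7.47-fold higher (5.82 to 9.73). Type 2 genes had a median of 0.97, with 7 of 14 at least 2-fold higher, Ccl8 at 46.2-fold (31.4 to 71.1) and Ccl17 at 12.8-fold (8.03 to 21.7). Metal-response (0.98), alternatively activated macrophage (0.88), metalloproteinase (0.82), acute-phase (0.78), endoplasmic reticulum stress (0.75), eosinophil (0.70), cell cycle (0.65) and interferon-response genes (0.61) followed. NRF2 targets had a median of 0.45, with Slc7a11 at 16.5-fold (12.9 to 21.4) and Hmox1, haem oxygenase, at 5.52-fold (5.0 to 6.10). Lymphoid tissue chemokines (0.57) included Cxcl13, which attracts B cells, at 5.84-fold (4.94 to 6.93). Class II (0.57), dendritic cell (0.52), plasma cell (0.46), alveolar macrophage (0.39), housekeeping (0.37), B cell (0.25) and T cell genes (0.23) were also higher. With the length and GC trend removed, housekeeping (0.22), B cell (0.17) and T cell genes (0.14) did not stand apart, nor did T cell (0.21) and lymphoid chemokine genes (0.37) with a mean of at least 5 CPM, nor B cell and T cell genes against random lists matched on length (percentile 97.4 in both).

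For the fibrosis named in the series title, the collagen and matrix list had a median of 0.24 (percentile 99.4), with 1 of 26 members at least 2-fold higher and 4 lower, among them Lum (3.64-fold, 3.16 to 4.21) and Dcn (2.56-fold, 2.43 to 2.70), both small matrix proteoglycans. The housekeeping list had a larger median in this comparison (0.37, percentile 99.9), though it did not stand apart with the length and GC trend removed (0.22). A median of this size that stands apart is therefore not particular to matrix genes. The TGF-beta and myofibroblast list stood apart as lower (median -0.19, percentile 0.13), but its mean was 0.13, opposite in sign. Of its 25 members 19 were below 0, with Timp1 and Tgfbi (3.08-fold, 2.89 to 3.28) at least 2-fold higher and no member 2-fold lower. Fibroblast genes stood apart as lower too (-0.41). These ratios are against the control library, in which 40 of 41 heart-muscle, fat and cartilage list genes were highest. Whether unequal tissue in the lung pieces enters the matrix and fibroblast values was not tested.

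Heart muscle (-3.12, all 19 members at least 2-fold lower), cartilage (-2.89, all 9) and fat genes (-2.87, 12 of 13) had the lowest medians. Pln, a regulator of the heart's calcium pump, was 15-fold lower (12.3 to 18.5) and Adipoq, the fat hormone adiponectin, 14.6-fold lower (10.6 to 20.8). Col2a1, cartilage collagen, had 0 counts against 333, at least 101-fold lower against the floor of 3 counts (exact lower limit 82.1). Circadian clock genes (-0.80), skeletal muscle (-0.70), smooth muscle (-0.55), club cell (-0.48), ciliated cell (-0.38) and endothelial genes (-0.19) were lower beside them, with the clock output gene Dbp at 2.67-fold (2.48 to 2.87) and the detoxifying enzyme Cyp2a5 at 8.96-fold (8.19 to 9.82). Longer transcripts again had lower ratios across genes (rho -0.30).

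**Figure D3:**
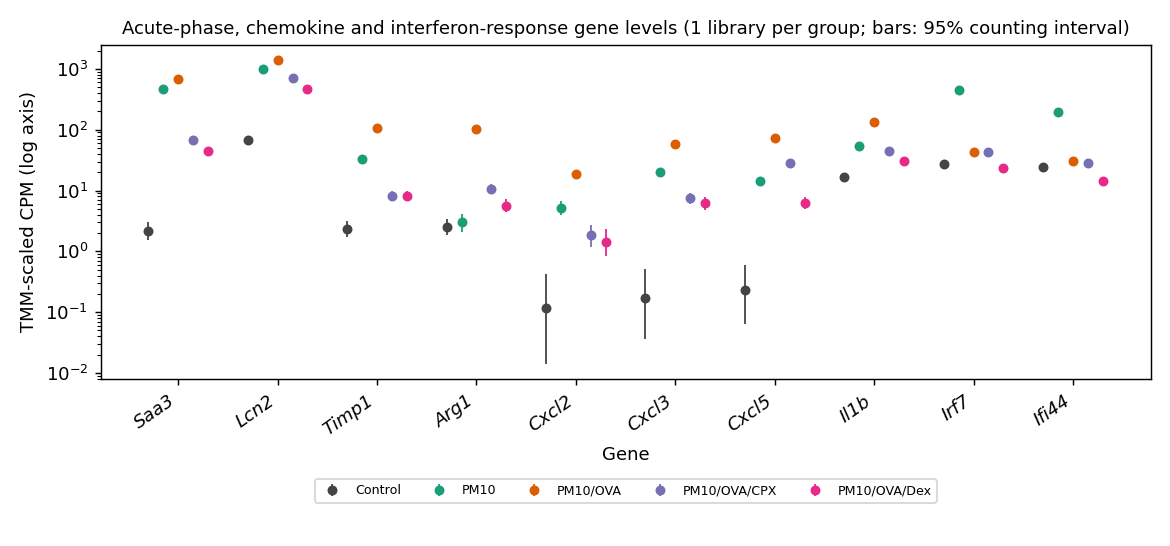
Levels of acute-phase, chemokine and interferon-response genes in TMM-scaled CPM on a log axis, 1 point per library, with bars for the 95% counting interval. Saa3 was at 694 CPM in PM10/OVA, 67.0 CPM in PM10/OVA/CPX and 44.7 CPM in PM10/OVA/Dex, while Irf7 was highest in PM10 (452 CPM).

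PM10/OVA/CPX against PM10/OVA asks what the chitinase-1 inhibitor altered in the exposed lung. Neutrophil chemokine and lymphoid chemokine genes were lower and mucous-cell and eosinophil genes were higher. Of the chitinase genes, Chia1, Chil3 and Chil4 were higher and Chil1 was lower. Irg1 was 47.2-fold lower (27.4 to 89.0), Timp1 13.2-fold (10.8 to 16.3), Saa3 10.4-fold (9.65 to 11.1), Cxcl2 10.1-fold (6.60 to 16.2) and Arg1 9.84-fold (8.24 to 11.8). Chil4 was 143-fold higher (110 to 190), Clca1 16.5-fold (16.0 to 17), Chil3 8.74-fold (8.54 to 8.95) and Muc5ac 7.56-fold (6.86 to 8.34). At the 2-fold threshold 91 genes were higher and 109 lower (177 and 182 with a pseudocount of 0.25, 35 and 58 with 5, and 50 higher with a mean of at least 5 CPM), against means of 0.08 and 0.14 from counting error. The total of 200 genes was the smallest of the 10 pairs of libraries. Of the lists, 6 stood apart as higher and 16 as lower.

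The neutrophil chemokine and cytokine list had a median of -0.97, with 8 of 16 members at least 2-fold lower, such as Il1b (2.93-fold, 2.67 to 3.22) and Il6 (9.16-fold on 5 counts against 58, 3.71 to 29.3). Neutrophil genes themselves had a median of -0.32, with Trem1 lower (3.61-fold, 2.82 to 4.67) and Retnlg higher (1.88-fold, 1.75 to 2.02). Lymphoid tissue chemokines (-0.52, Cxcl13 5.37-fold lower, 4.47 to 6.51), B cell genes (-0.52), metal-response genes (-0.51, Hmox1 3.54-fold lower, 3.22 to 3.89), acute-phase genes (-0.48), cytotoxic cell genes (-0.44), endoplasmic reticulum stress genes (-0.40) and glucocorticoid-responsive genes (-0.32) were lower as well. The metalloproteinase list had a median of -0.29, with Mmp3 3.97-fold lower (3.26 to 4.86) and Mmp12 2.03-fold higher (1.94 to 2.13). Heart muscle (-0.22), interferon-response (-0.19), erythroid (-0.19), collagen and matrix (-0.17) and immediate-early and heat-shock genes (-0.17) stood apart by small medians. The last did not with a pseudocount of 5 (-0.11). Erythroid genes did not with haemoglobin genes left out (-0.19) or against random lists matched on length (percentile 2.75). The interferon list held Cxcl9 at 6.70-fold lower (4.55 to 10.2), while Col5a3 was the matrix gene with the largest difference, 2.13-fold lower (1.48 to 3.11). Mesothelial genes, which mark the covering of the lung, had the lowest median, -1.01, with all 9 below 0 and 5 at least 2-fold lower, such as Upk3b (3.33-fold, 2.79 to 4.0) and Msln (2.51-fold, 2.20 to 2.86).

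Chitinase genes had a median of 1.0 (3 of 6 at least 2-fold higher) and mucous-cell genes of 0.92 (7 of 18), with Fcgbp, a mucus protein, at 7.80-fold (7.14 to 8.53) and Itln1, a lectin, at 10.3-fold (7.88 to 13.6). Agr2 in the same list was at 23.2 CPM against 26.1. In the chitinase list Chil1 (2611 CPM against 3067) and Chid1 (31.1 against 39.3) were lower, and Ctbs was at 20.1 against 19.0. Eosinophil genes had a median of 0.81, with the granule protein Prg2 at 3.83-fold (2.70 to 5.51) and Ear2, whose reads other Ear genes can share, at 2.77-fold (2.61 to 2.94). Ciliated cell (0.42), alveolar macrophage (0.24) and fibroblast genes (0.18) were higher too, and in the macrophage list Il1rn was 4.71-fold lower (4.29 to 5.19). Jchain, the joining chain of secreted antibodies, was 12.7-fold higher (11.9 to 13.4), while the plasma cell list did not stand apart (median 0.04, percentile 75.4). Amd1, an enzyme of polyamine synthesis, had 278 counts in the CPX library and 1 count in each of the other 4. Its close paralog Amd2 was lowest in the same library (59.0 CPM, against 93.1 to 108 in the others), so how reads were assigned between the 2 genes is uncertain. The type 2 list did not stand apart (-0.14, percentile 4.28), but stood apart as higher with only genes of a mean of at least 5 CPM (0.17) and as lower without a filter (-0.11), so its direction depended on the filter. Alternatively activated macrophage genes had a median of 0.07 and a mean of -0.06, opposite in sign, and the TGF-beta list a median of -0.09 (percentile 9.14).

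PM10/OVA/Dex against PM10/OVA shows the lung under the glucocorticoid. Chemokine, interferon-response and B cell genes were lower. Higher were mucous-cell and club cell genes and the heat-shock genes Hspa1a and Hspa1b. Irg1 was 52.9-fold lower (29.4 to 106), Arg1 18.5-fold (14.5 to 24.0), Saa3 15.5-fold (14.2 to 17), Timp1 13.2-fold (10.8 to 16.4) and Cxcl5 11.8-fold (9.32 to 15.1). The heat-shock genes Hspa1b and Hspa1a were 24.1-fold (20.1 to 29.1) and 21.5-fold higher (17.6 to 26.6). At the 2-fold threshold 172 genes were higher and 229 lower (294 higher with a pseudocount of 0.25, 55 and 101 with 5, and 106 higher with a mean of at least 5 CPM), against means of 0.07 and 0.33 from counting error, and 13 lists stood apart as higher and 20 as lower.

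The neutrophil chemokine and cytokine list had a median of -1.50, with 10 of 16 members at least 2-fold lower. B cell genes (-1.13, 11 of 16) included the IgE receptor Fcer2a at 6.28-fold lower (4.94 to 8.07). All 28 interferon-response genes were below 0 (median -0.99, 14 of them by at least 2-fold), with Cxcl10 at 33.9-fold lower on 5 counts against 226 (14.3 to 105). Neutrophil genes (-0.84) included S100a8 at 2.74-fold lower (2.5 to 3.01), and Ltf went the other way, 3.43-fold higher (3.23 to 3.65). Lymphoid tissue chemokines (-0.76), cytotoxic cell genes (-0.74, Gzmb 3.51-fold lower), acute-phase (-0.48), dendritic cell (-0.45), class II (-0.44), cell cycle (-0.44, Mcm5 3.19-fold lower), endoplasmic reticulum stress (-0.44) and T cell genes (-0.39) were lower too. Smaller medians stood apart for metalloproteinase (-0.35), erythroid (-0.30), NRF2 target (-0.28), metal-response (-0.28), type 2 (-0.27), collagen and matrix (-0.24), housekeeping (-0.21) and monocyte genes (-0.17). The calls of monocyte (-0.14), metal-response (-0.22) and circadian clock genes (0.14) ended with the length and GC trend removed (monocyte genes also against random lists matched on length, percentile 3.54), and those of metal-response (-0.20) and skeletal muscle genes (0.12) without a filter. Among them Ccl24 was 5.29-fold lower (3.37 to 8.68), Hmox1 3.82-fold lower (3.47 to 4.23) and Spp1, osteopontin, 2.59-fold lower (2.40 to 2.79).

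The fixed glucocorticoid-responsive list had a median of 0.27 (percentile 100), with 3 of 25 members at least 2-fold higher, among them Zbtb16 (3.36-fold, 2.65 to 4.28) and Pdk4 (2.63-fold, 2.18 to 3.19), and 2 lower, Lcn2 (3.01-fold) and Mt2 (2.76-fold). Zbtb16 was not particular to dexamethasone, with a log2 ratio of 1.67 in CPX and 1.60 in Dex against PM10/OVA. The immediate-early and heat-shock list had a median of 0.31. Mucous-cell genes were higher (0.54, 6 of 18 at least 2-fold higher and 2 lower), Clca1 by 5.22-fold (5.06 to 5.39) and Muc5ac by 3.04-fold (2.73 to 3.39). Chitinase genes had a median of 0.41, with Chil4 at 11.5-fold higher (8.74 to 15.5), Chil3 at 2.80-fold higher (2.73 to 2.88) and Chil1 at 2.00-fold lower (1.97 to 2.04). Club cell genes (0.48) included Scgb3a1, a secretoglobin, at 3.80-fold (3.67 to 3.95). Like the fat, heart-muscle and cartilage lists, the club cell list was lower in PM10/OVA than in control (-0.48). Whether unequal tissue in the lung pieces enters its value was not tested. Fibroblast (0.34), alveolar macrophage (0.25), ciliated cell (0.24) and circadian clock genes (0.18) were higher as well. Fat (1.47, 7 of 13 at least 2-fold higher), heart muscle (1.19, 11 of 19), cartilage (1.09, 6 of 9) and skeletal muscle genes (0.39) were higher beside them, Nppa by 18.4-fold (11.3 to 32.2). The eosinophil list (median -0.04, mean 0.05), the plasma cell list (median -0.18, mean 0.03) and the TGF-beta list (median 0.03, mean -0.14) did not stand apart, with median and mean opposite in sign. The eosinophil median was 0.47, and stood apart, with only genes of a mean of at least 5 CPM. Also among the 10 highest were Bpifa6 (141 counts against 0), of a family of related genes, and Atp6v0c-ps2 (129 against 1), a processed pseudogene of Atp6v0c, and the assignment of reads to both is uncertain.

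PM10/OVA/Dex against PM10/OVA/CPX sets the treatments side by side. Chitinase and mucous-cell genes were lower under dexamethasone than under CPX, Chil4 by 12.4-fold (11.3 to 13.7), Chil3 by 3.12-fold (3.07 to 3.18) and Clca1 by 3.16-fold (3.11 to 3.21), and Hspa1a was 21.8-fold higher (17.4 to 27.7). At the 2-fold threshold 151 genes were higher and 105 lower (275 and 224 with a pseudocount of 0.25, 56 and 30 with 5, and 58 lower with a mean of at least 5 CPM), against means of 0.30 and 0.38 from counting error. Of the lists, 13 stood apart as higher and 18 as lower. Chitinase genes had a median of -0.96, mucous-cell genes of -0.77 (8 of 18 at least 2-fold lower), interferon-response genes of -0.75 (7 of 28), eosinophil genes of -0.63 (4 of 11, Prg2 10.5-fold lower, 5.83 to 20.9) and alternatively activated macrophage genes of -0.58. Immune cell lists were lower as well, including class II (-0.58), B cell (-0.55), cytotoxic cell (-0.44), T cell (-0.44) and plasma cell genes (-0.43, Jchain 2.5-fold lower, 2.41 to 2.58), as were cell cycle (-0.49), neutrophil (-0.38), dendritic cell (-0.34), neutrophil chemokine (-0.33), monocyte (-0.22), alveolar macrophage (-0.20), erythroid (-0.16) and acute-phase genes (-0.14, not apart from random lists matched on length, percentile 3.29).

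Higher in dexamethasone were heart muscle (1.45, 15 of 19 at least 2-fold), fat (1.41, 10 of 13), mesothelial (1.24, 5 of 9), cartilage (0.79) and skeletal muscle genes (0.54). Club cell (0.41, Cyp2a5 7.22-fold, 6.01 to 8.73), immediate-early and heat-shock (0.41), aryl hydrocarbon receptor target (0.37), mast cell (0.33), glucocorticoid-responsive (0.32, 7 of 25), alveolar type 1 (0.17), fibroblast (0.17) and TGF-beta genes (0.16) were higher too. In the glucocorticoid list Sult1d1 was 5.71-fold higher (4.17 to 7.98) and Errfi1 2.78-fold higher (2.59 to 2.98). Bpifa1 was 7.71-fold higher (7.15 to 8.33). NRF2 targets (median -0.02, mean 0.00) and the collagen and matrix list (median 0.01, mean -0.01) did not stand apart. Longer transcripts had higher ratios across genes (rho 0.22). With the length and GC trend removed, neutrophil chemokine (-0.21), alveolar macrophage (-0.10) and alveolar type 1 genes (0.13) did not stand apart, nor did mast cell (0.15) and cytotoxic cell genes (-0.20) without a filter.

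**Figure D4:**
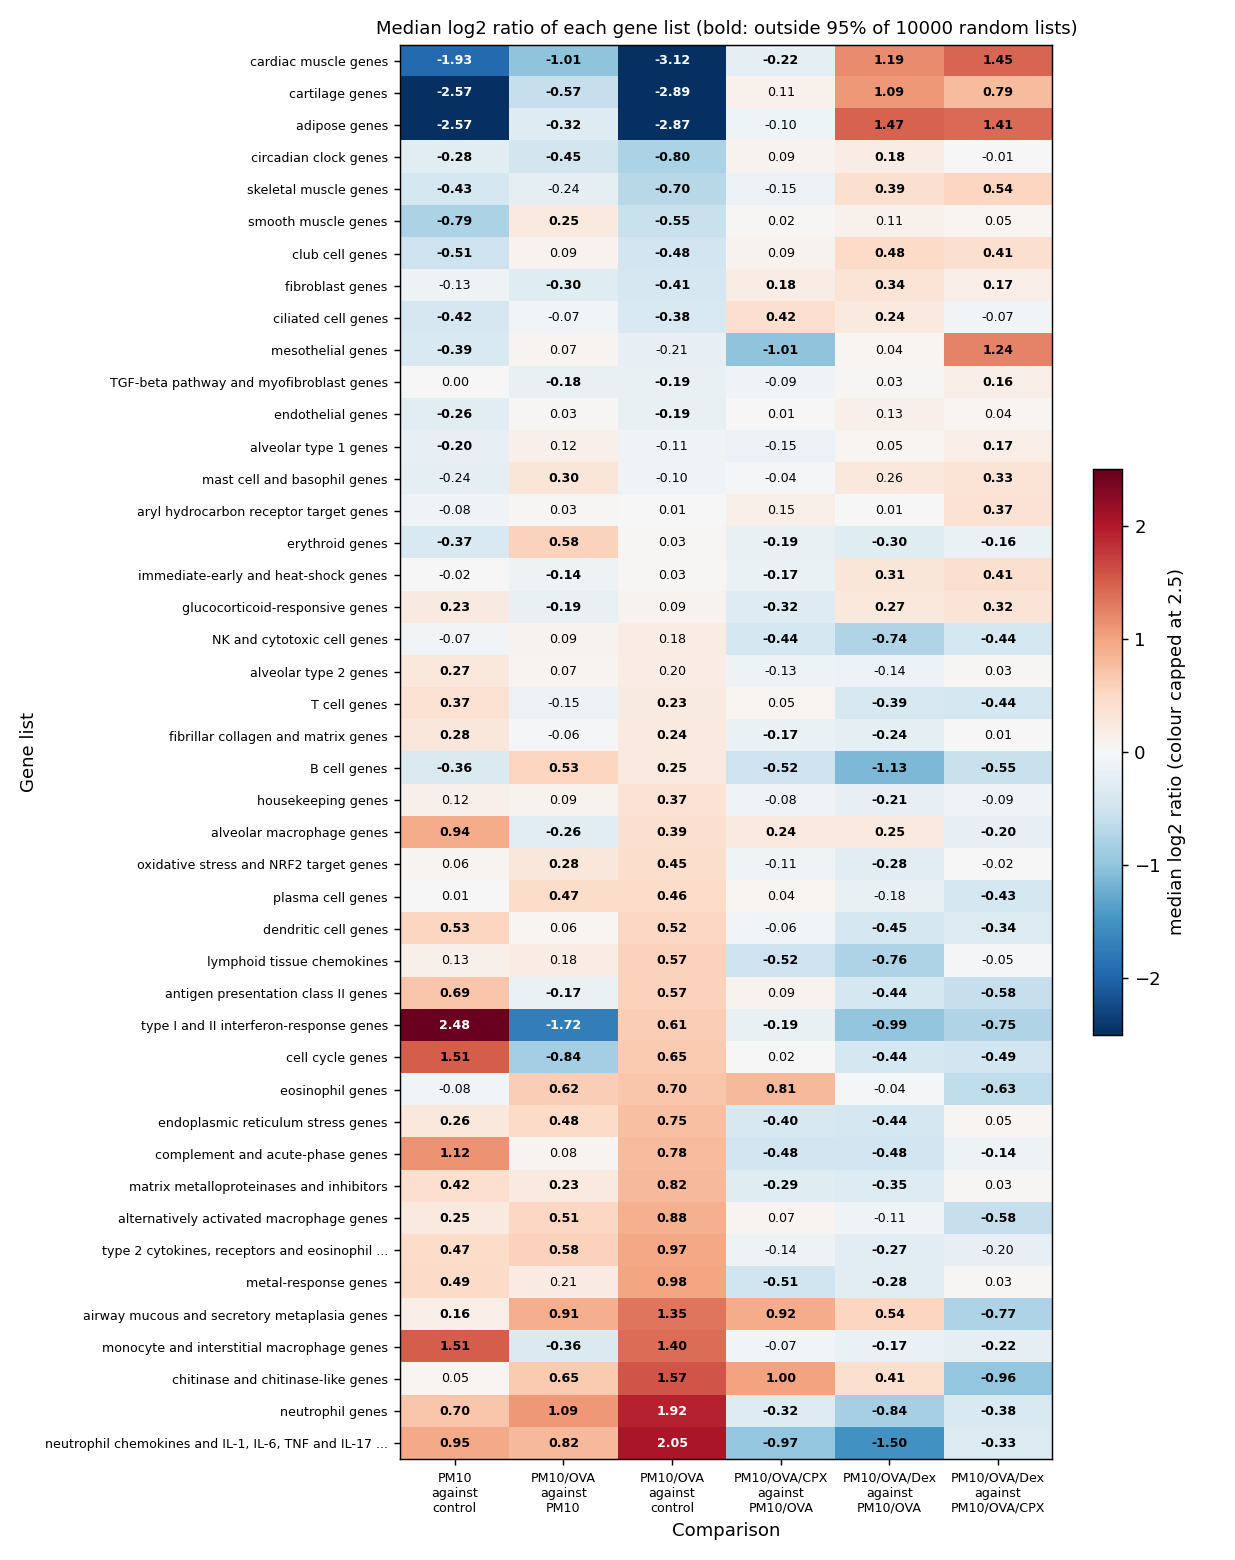
Median log2 ratio of each of the 44 gene lists (vertical axis) in the 6 comparisons (horizontal axis), coloured by value with the colour capped at 2.5, and in bold where the list stood apart from 95% of the random lists. The interferon-response median was 2.48 in PM10 against control and -1.72 in PM10/OVA against PM10.

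The genes that differed between PM10/OVA and control were then followed under each treatment. The 454 higher genes had a median log2 ratio of -0.39 in CPX against PM10/OVA (95% interval over genes -0.44 to -0.32) and of -0.72 in Dex against PM10/OVA (-0.78 to -0.64), where counting error with no treatment effect gave -0.01 in both. That value does not hold the differences between single lungs, which can also pull genes picked on the PM10/OVA library back when they are followed against it. Picked at 1.5-fold and 4-fold, the higher genes had medians of -0.21 and -0.96 with CPX and of -0.47 and -1.36 with dexamethasone. Of the 454 genes 79 were at least 2-fold lower with CPX and 138 with dexamethasone. The 390 lower genes had a median of 0.05 with CPX (0.00 to 0.10, no effect 0.02) and of 0.66 with dexamethasone (0.61 to 0.74, no effect 0.02). The heart-muscle, cartilage and fat genes, which were lowest in PM10/OVA against control, are part of these lower genes and were also higher with dexamethasone. With the heart, skeletal muscle, fat and cartilage list genes left out the dexamethasone median was 0.61. Only members of these fixed lists were taken out. Genes outside them with a similar course stayed in, such as Col10a1 at 1212 counts in control, 1 in PM10/OVA and 82 in Dex. The value of 0.61 is therefore not free of the pattern of these tissues. For CPX the median of the 390 genes turned negative, to -0.02, -0.01 and -0.07, with a pseudocount of 5, a mean of at least 5 CPM and genes picked at 4-fold, and was 0.14 with a pseudocount of 0.25 and 0.13 at 1.5-fold. For dexamethasone it was 1.06 at 4-fold.

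In other pairings the genes were picked and followed in libraries that are not shared. The 529 genes higher in PM10 than in control had medians of -0.11 (-0.16 to -0.05) in CPX against PM10/OVA and -0.51 (-0.55 to -0.45) in Dex against PM10/OVA, and the 292 lower genes -0.06 (-0.11 to 0.00) and 0.68 (0.59 to 0.79), where no effect gave 0.00 in each. The value of 0.00 follows from drawing the treated libraries at the PM10/OVA level with counting error only. It leaves out differences between lungs, which can also shift such a median. Picked at 4-fold, the higher genes had -0.40 and -0.97 and the lower genes 1.19 with dexamethasone, and at 1.5-fold the lower genes had 0.0226 with CPX, the opposite sign, and 0.32 with dexamethasone. Between the treatments, in Dex against CPX, the 454 higher genes had a median of -0.35 and the 390 lower genes of 0.59 (0.28 at 1.5-fold, 1.10 at 4-fold). Heart-muscle, fat and cartilage genes are among the 292 and the 390 lower genes. Their list medians were 1.19, 1.47 and 1.09 in Dex against PM10/OVA and 1.45, 1.41 and 0.79 in Dex against CPX. With the list genes left out the medians of followed genes stayed within their intervals, but genes outside the lists with a similar course stayed in. The dexamethasone values of the lower genes are therefore not free of the pattern of these tissues here either. Against PM10 the 454 higher genes had medians of -0.10 with CPX and -0.38 with dexamethasone, and the 390 lower genes -0.41 and 0.21. Treated libraries simulated at the PM10/OVA level gave 0.35 and 0.34 for the higher genes and -0.46 in both for the lower genes. That simulation starts from the library on which the genes were picked, so it carries that library's own deviation. The gap between observed and simulated medians against PM10 therefore cannot show a treatment effect. For the higher genes the observed medians against PM10 were -0.27 and -0.60 at 4-fold, with -0.25 for dexamethasone at 1.5-fold. The lower genes had -0.22 and 0.0842 at 1.5-fold and, with CPX, -0.83 at 4-fold, and with dexamethasone 0.13 with a pseudocount of 5 and 0.12 with a mean of at least 5 CPM.

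CPX against PM10/OVA and Dex against PM10/OVA correlated across 14305 genes with Pearson's r of 0.54, where the shared library alone gave 0.43 in simulation. The covariance was 0.0748 against a simulated 0.00870. At least 2-fold higher in both were 26 genes, where 1.09 would be shared by independent lists and 0.02 by simulation with no effect, and 65 were lower in both, against 1.74 and 0. Part or all of the excess may come from the shared PM10/OVA library, which cannot be split. Neither the independent lists nor the simulation hold differences between lungs. These values rest on the labels of the CPX and PM10/OVA libraries. With these labels exchanged, 15 genes were higher and 24 lower in both. The 391 genes then picked as higher had medians of -0.24 in CPX and -0.52 in Dex against PM10/OVA, and the 428 lower genes 0.20 and 0.70, so the medians of the picked genes do not tell the labels apart. The pairs that share no library correlated at 0.12 (CPX against PM10 with Dex against PM10/OVA) and 0.31 (CPX against PM10/OVA with Dex against PM10), where no effect gave 0.00 in both. In the first of these pairs 24 genes were at least 2-fold higher and 51 lower in both, with 11 and 47 in opposite directions, and in the second 32 and 31, with 3 and 1 opposite. The genes lower in both CPX and Dex against PM10/OVA included Irg1, Saa3, Timp1, Arg1, Cxcl2, Cxcl3, Il1b and Hmox1, and those higher in both included Chil3, Chil4, Clca1, Muc5ac, Fcgbp and Jchain.

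**Figure D5:**
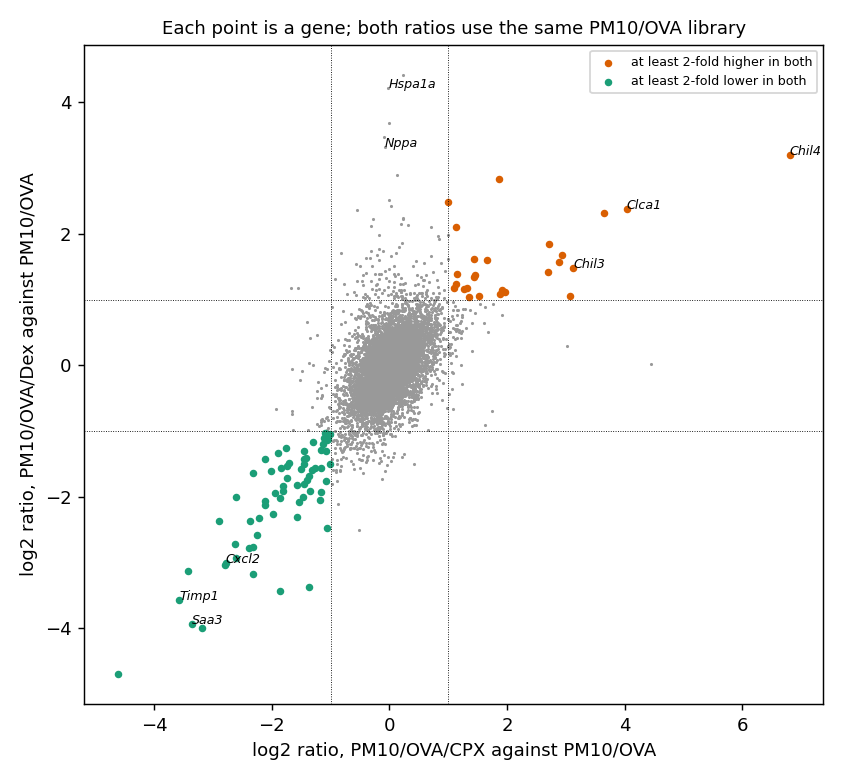
Log2 ratio of each of the 14305 measured genes in PM10/OVA/CPX against PM10/OVA (horizontal axis) and in PM10/OVA/Dex against PM10/OVA (vertical axis), 1 point per gene, with dotted lines at 2-fold and coloured points for the genes past 2-fold in the same direction in both. The 65 genes at the lower left include Saa3 and Timp1, the 26 at the upper right include Chil4 and Clca1, and grey points are all other genes.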

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

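No paired analysis was possible because each group has 1 library. With 1 library per group no setting can show how far animals differ, and low-count genes carry the widest counting intervals. Alternatives added after seeing the data were leaving out the heart, skeletal muscle, fat and cartilage list genes, removing the length and GC trend, random lists matched on length, the percent of followed genes below 0, and exchanged labels of the CPX and PM10/OVA libraries for the followed genes. A first version of the alternatives used that percent in place of the planned medians, and the planned medians were then restored and are given here.

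Over the alternatives, 84 of 108 counts at 2-fold stayed within 1.5 times the reported count and 24 did not. Of 2334 list calls, 2275 stayed on their side of the bounds, 32 lists newly stood apart, 27 no longer did, and none that stood apart turned its sign. Of 154 medians of followed genes, 111 stayed within the interval of the reported value, as did 8489 of 9136 log2 ratios of single genes. Total-count scaling and DESeq2 size factors left all counts within 1.5 times, all list calls on their side and all 14 medians of followed genes within their interval. With random lists matched on length, 176 of the 181 lists that stood apart still did. Those that did not were B cell (percentile 97.4) and T cell genes (97.4) in PM10/OVA against control, erythroid genes (2.75) in CPX against PM10/OVA, monocyte genes (3.54) in Dex against PM10/OVA and acute-phase genes (3.29) in Dex against CPX. The 3 that newly did were T cell genes in PM10/OVA against PM10, mesothelial genes in PM10/OVA against control and endothelial genes in Dex against PM10/OVA. Below, values are given by setting with the reported value in brackets. Except where the construction of the setting is named, the cause was not tested.

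A pseudocount of 0.25 keeps ratios of low genes larger, so more genes passed 2-fold: 173 (99) higher and 308 (182) lower in PM10/OVA against PM10, 177 (91) and 182 (109) in CPX against PM10/OVA, 294 (172) higher in Dex against PM10/OVA, and 275 (151) and 224 (105) in Dex against CPX. A pseudocount of 5 shrinks them, and the counts higher and lower were 304 (529) and 141 (292) in PM10 against control, 54 (99) and 78 (182) in PM10/OVA against PM10, and 261 (454) and 203 (390) in PM10/OVA against control. With the same pseudocount of 5 they were 35 (91) and 58 (109) in CPX against PM10/OVA, 55 (172) and 101 (229) in Dex against PM10/OVA, and 56 (151) and 30 (105) in Dex against CPX. A mean of at least 5 CPM leaves fewer genes, with 146 (292) lower in PM10 against control, 208 (390) lower in PM10/OVA against control, 50 (91) higher in CPX against PM10/OVA, 106 (172) higher in Dex against PM10/OVA and 58 (105) lower in Dex against CPX.

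For the genes picked in PM10/OVA against control, a pseudocount of 0.25 gave the lower genes medians of 0.14 (0.05) in CPX and 0.77 (0.66) in Dex against PM10/OVA. A pseudocount of 5 gave the higher genes -0.45 (-0.39) in CPX against PM10/OVA and -0.29 (-0.35) in Dex against CPX. It gave the lower genes -0.0231 (0.05) in CPX and 0.48 (0.66) in Dex against PM10/OVA, 0.45 (0.59) in Dex against CPX and 0.13 (0.21) in Dex against PM10. Without a filter the lower genes had 0.59 (0.66) in Dex against PM10/OVA, 0.50 (0.59) in Dex against CPX and -0.33 (-0.41) in CPX against PM10. With a mean of at least 5 they had -0.0102 (0.05) in CPX against PM10/OVA, -0.58 (-0.41) in CPX against PM10 and 0.12 (0.21) in Dex against PM10. With the length and GC trend removed, the higher genes had -0.31 (-0.35) in Dex against CPX. For the genes lower in PM10 than in control, Dex against PM10/OVA gave 0.56 (0.68) with a pseudocount of 5, 0.54 without a filter and 0.83 with a mean of at least 5.

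Picking at 1.5-fold takes in genes with smaller ratios, and picking at 4-fold keeps those with larger ones. At 1.5-fold the higher genes of PM10/OVA against control had -0.21 (-0.39) in CPX and -0.47 (-0.72) in Dex against PM10/OVA, -0.28 (-0.35) in Dex against CPX and -0.25 (-0.38) in Dex against PM10. The lower genes had 0.13 (0.05), 0.45 (0.66), 0.28 (0.59) and 0.0842 (0.21) in the same order, and -0.22 (-0.41) in CPX against PM10. Genes picked at 1.5-fold in PM10 against control had 0.0226 (-0.06, the sign turned) for the lower genes in CPX against PM10/OVA, and -0.39 (-0.51) for the higher and 0.32 (0.68) for the lower genes in Dex against PM10/OVA. At 4-fold the higher genes of PM10/OVA against control had -0.96 (-0.39) in CPX and -1.36 (-0.72) in Dex against PM10/OVA, -0.41 (-0.35) in Dex against CPX, -0.27 (-0.10) in CPX against PM10 and -0.60 (-0.38) in Dex against PM10. The lower genes at 4-fold had -0.0690 (0.05), 1.06 (0.66), 1.10 (0.59), -0.83 (-0.41) and 0.28 (0.21) in that order. Genes picked at 4-fold in PM10 against control had -0.40 (-0.11) for the higher genes in CPX against PM10/OVA, and -0.97 (-0.51) for the higher and 1.19 (0.68) for the lower genes in Dex against PM10/OVA. The sign of the CPX median for the lower genes of PM10/OVA against control thus depended on the setting. The percent of these genes below 0 was 44.4 with the settings of the report, and was 54.2 with a pseudocount of 5, 51.0 with a mean of at least 5 and 56.4 at 4-fold.

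Among the lists, mucous-cell genes in PM10 against control no longer stood apart with a pseudocount of 5 (0.0693), without a filter (0.13), with a mean of at least 5 (0.16, as reported) or with the trend removed (0.15). A pseudocount of 0.25 ended the call of class II genes in PM10/OVA against PM10 (-0.17, as reported), and added mast cell and basophil genes in PM10 against control (-0.64, reported -0.24) and endothelial genes in Dex against PM10/OVA (0.13). A pseudocount of 5 ended it for fat (-0.12, reported -0.32) and cartilage genes (-0.15, reported -0.57) in PM10/OVA against PM10 and for immediate-early and heat-shock genes in CPX against PM10/OVA (-0.11, reported -0.17). It added mast cell and basophil (-0.23) and fibroblast genes (-0.13) in PM10 against control, T cell (-0.13) and metal-response genes (0.21) in PM10/OVA against PM10, plasma cell (-0.18) and endothelial genes (0.13) in Dex against PM10/OVA, and type 2 genes (-0.16) in Dex against CPX.

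Without a filter the calls ended for metalloproteinase genes in PM10/OVA against PM10 (0.0196, reported 0.23), for skeletal muscle (0.12, reported 0.39) and metal-response genes (-0.20, reported -0.28) in Dex against PM10/OVA, and for mast cell and basophil (0.15, reported 0.33) and cytotoxic cell genes (-0.20, reported -0.44) in Dex against CPX. Added were type 2 (-0.11) and club cell genes (0.10) in CPX against PM10/OVA, mast cell and basophil genes in PM10 against control (-0.27) and skeletal muscle genes in PM10/OVA against PM10 (-0.22). A mean of at least 5 ended the calls of eosinophil (0.0413, reported 0.62) and class II genes (-0.12) in PM10/OVA against PM10 and of T cell (0.21) and lymphoid chemokine genes (0.37, reported 0.57) in PM10/OVA against control. The lists it added include a turned sign for type 2 genes in CPX against PM10/OVA (0.17, reported -0.14) and for eosinophil genes in Dex against PM10/OVA (0.47, reported -0.04). The others were NRF2 target (-0.18) and circadian clock genes (0.14) in CPX against PM10/OVA, endothelial genes in Dex against PM10/OVA (0.14), type 2 genes in Dex against CPX (-0.28), and fibroblast (-0.13) and NRF2 target genes (0.13) in PM10 against control.

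Removing the trend ended the calls of B cell (0.17), T cell (0.14) and housekeeping genes (0.22) in PM10/OVA against control, of monocyte (-0.14), metal-response (-0.22) and circadian clock genes (0.14) in Dex against PM10/OVA, and of neutrophil chemokine (-0.21), alveolar macrophage (-0.10) and alveolar type 1 genes (0.13) in Dex against CPX. It added T cell (-0.24), lymphoid chemokine (0.25), collagen and matrix (-0.0686) and skeletal muscle genes (-0.37) in PM10/OVA against PM10, mesothelial genes in PM10/OVA against control (-0.26), NRF2 target (-0.19) and circadian clock genes (0.12) in CPX against PM10/OVA, and endothelial genes in Dex against CPX (0.13). Leaving out haemoglobin genes ended the call of erythroid genes in CPX against PM10/OVA (-0.19) and added mast cell and basophil genes in Dex against PM10/OVA (0.55, reported 0.26). Leaving out the heart, skeletal muscle, fat and cartilage genes added fibroblast genes in PM10 against control (-0.13) and endothelial genes in Dex against PM10/OVA (0.13).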

Other observations

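All the tests of explanations in this part were chosen after the results were seen. Mesothelial genes were lowest in the CPX library, where Upk3b was at 12.2 CPM (40.7 in PM10/OVA, 54.8 in control), Lrrn4 at 5.27 CPM (17 and 19.4) and Wt1 at 0.559 CPM (2.14 and 3.81). In Dex against CPX all 9 mesothelial genes were above 0. Circadian clock genes had medians of -0.28 in PM10 against control and -0.80 in PM10/OVA against control. The clock repressor Nfil3 was 2.69-fold (1.97 to 3.71) and 3.75-fold higher (2.82 to 5.05) in these, and Hlf, a clock output factor, was 3.04-fold lower in the second (2.71 to 3.42). The heat-shock gene Hspa1a was far apart in level, at 36.7 CPM in control, 50.7 in PM10, 6.31 in PM10/OVA, 6.23 in CPX and 136 in Dex. The immediate-early and heat-shock list as a whole had small medians against control. Its median and mean had opposite signs in PM10 against control (-0.02 and 0.02) and PM10/OVA against control (0.03 and -0.33). So had those of cytotoxic cell genes in PM10 against control (-0.07 and 0.08), aryl hydrocarbon receptor targets in CPX against PM10/OVA (0.15 and -0.03) and alveolar type 1 genes in Dex against PM10/OVA (0.05 and -0.15). In Dex against CPX they differed for metalloproteinase (0.03 and -0.07), alveolar type 2 (0.03 and -0.08) and circadian clock genes (-0.01 and 0.11).

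Single genes had large differences outside the lists. Cyp26b1, which breaks down retinoic acid, was 23.9-fold lower in PM10 than in control (20.6 to 27.8) and 5.61-fold lower in Dex than in CPX (4.95 to 6.37). Rnase2a was 45.1-fold higher in PM10/OVA than in PM10 on 237 counts against 4 (17.4 to 167), and Col6a5, a collagen chain, 10.6-fold higher (6.75 to 17.7). Apod, a lipid carrier, was 12.5-fold lower there (10.1 to 15.5). Ly6i was 79.5-fold higher in PM10 than in control (41.5 to 175) and 8.28-fold lower in PM10/OVA than in PM10 (6.52 to 10.6). In CPX against PM10/OVA, Scin, an actin-severing protein, was 9.08-fold higher (6.36 to 13.3), Sprr2a3, an epithelial envelope protein, 13.2-fold higher (8.53 to 21.5) and Chl1, a cell adhesion molecule, 11.0-fold lower (7.20 to 17.6).

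Heart-muscle, fat and cartilage genes were highest in control, for 40 of 41 members of these lists. A trend with transcript length or GC content is argued against as the whole cause, since the median in PM10/OVA against control was -3.01 (95% bootstrap interval -3.23 to -2.60) with the trend removed and -2.91 without. Unequal amounts of adjoining tissue in the lung pieces could explain the pattern. If so, the members' excess in Dex, relative to that in control, should lie within 2-fold of their list's median, and 78.4% of 37 members did, where at least 80 was set for this cause and under 50 against it. Tissue carry-over and an effect of the exposures on these genes cannot be told apart here, because each group has 1 library, and the latter was not tested. Club cell genes had a similar course, with medians of -0.51 and -0.48 in PM10 and PM10/OVA against control and 0.48 in Dex against PM10/OVA. Ciliated cell (-0.42 and -0.38) and smooth muscle genes (-0.79 and -0.55) were also lower against control. Whether unequal tissue enters the values of these lists was not tested.

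Mucous-cell genes were higher in CPX than in PM10/OVA (median 0.92). More airway epithelium is argued against as the whole cause, since the median exceeded that of 33 club and ciliated genes (0.19) by 0.73 (0.35 to 1.17), and so is a length or GC trend, with 0.93 (0.58 to 1.33) after its removal. The former holds only for epithelium with the same mix of cells in both libraries, and the intervals resample genes, not lungs. Exchanged labels of these libraries stay open, since the mucous-cell median was also above 0 in Dex against PM10/OVA (0.54, 0.05 to 1.08). The neutrophil chemokine median of -0.97 in CPX against PM10/OVA runs against exchanged labels if an inhibitor lowers these genes, so the labels and an exchange cannot be told apart by these values. An effect of the inhibitor on mucous cells, named by the design, may also explain the pattern and was not tested.

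Interferon-response genes were higher in PM10 than in PM10/OVA (median 1.72 as PM10 over PM10/OVA). More monocytes and macrophages in PM10 are argued against as the whole cause, since this median exceeded that of the monocyte list (0.36) by 1.36 (0.49 to 1.72). This holds only for cells with the same gene levels in both libraries, and the interval resamples genes, not lungs. More cells with higher interferon-response levels are not excluded. A length or GC trend is argued against as well, with 1.80 (0.93 to 1.95) after its removal. A lower interferon response with the allergen, or a response of the single PM10 library to something other than the particles, could explain the pattern, and neither was tested.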
